A study of Homo sapiens with 6 samples.

How the data were processed

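RNA from 6 samples of the human cell line Kasumi-1 was measured on one-colour Affymetrix 3' expression arrays, 3 after vehicle and 3 after 20 nM homoharringtonine (HHT) for 24 h. Per the labels' protocols, total RNA was amplified and labelled with biotin using a 3' in vitro transcription kit. The labels number the arrays 1 to 3 in each group and do not say whether they came from separate cultures, so p-values measure the spread between these samples, which may be technical. Scan dates and array batches are not given in the sources used here. The sample titles also number all arrays in sequence, vehicle before HHT. Any effect of that order cannot be told apart from the treatment.

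The deposited values are log2 signals, 1 per probe set, for 54675 probe sets on each array. MAS5 is named in the submitters' processing notes, without a version. The values themselves show the scaling: the mean of the antilog signals after trimming 2% at each end lay between 500.06 and 500.07 on all 6 arrays. Values stop at 0, which between 235 and 711 probe sets per array reached. No detection calls were used here. Because the values already are log2, no pseudocount was added. No 2 arrays held identical values.

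The 62 control probe sets were kept out of the tests, which left 54613. The 40% of these with the lowest mean over all 6 arrays were left out, at a level of 4.80, and 32768 were tested. Probe sets were named through the platform annotation: 41091 had 1 gene, 1801 had several and 11721 had none listed. Symbols of 41037 single-gene probe sets were updated through their Entrez IDs with RefSeq genes of GRCh38.p14. The sources used here name no genome build, so no coordinates are given. Probe sets with several genes were not used to name a gene. A gene was represented by its single-gene probe set of highest mean, which gave 13572 genes. Genes of the lists without such a probe set were not analysed here, and neither were control probe sets other than those for spiked-in transcripts, ribosomal RNA, ACTB and GAPDH.

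Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the variance on the level), with Benjamini-Hochberg adjustment over the probe sets tested. A gene was called at an adjusted p under 0.05. The words rose and fell are used for called genes. Errors of log2 changes are standard errors (SE), and those of group means are standard deviations (SD) over 3 arrays. The number of arrays limits the precision. The median SD between replicates was 0.583 in the dimmest 25% of the tested probe sets and 0.0858 in the brightest 25%. Where a group's mean lay below 4.80, the fold is given as a lower bound, with each array of that group set to at least this level. The same was done for TXLNB, LOC101929174, DDN and INHBE, which had 1 array below it. CSF1R and ELANE also had 1 and are given at their measured change. That level is the filter's and no measured detection limit.

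Before the data were examined, 30 gene lists were written from general knowledge, and 28 of them had the 5 measured members needed for a set test. They were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 28 lists. Camera with an estimated correlation and fry were alternatives. Fry asks whether a list's genes moved on balance one way and does not compare them with other genes. The rule for named genes was also fixed then. It takes MYC, NKRF, RELA, KIT, RUNX1 and RUNX1T1, the 6 largest increases and 6 largest decreases in fitted log2 change among called genes whose groups do not overlap, and the 2 called members of each list with the largest change. It gave 70 genes with a value. None of them had another probe set called in the opposite direction, and 11 called ones had another probe set that was not called (ARHGAP22, BUB1, COL1A1, ERN1, MEIS1, MYCN, NR4A3, OAS2, TAL1, TCOF1 and WDR3). The 6 largest fitted increases and decreases with both group means above 4.80 were added after the values were seen.

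Alternatives fixed beforehand were pseudocounts of 1 and 64, equal medians, quantile normalization, no filter, a filter of 60%, no variance trend, a robust trend, array weights, the replicate number as a block, a threshold that adds an absolute log2 change of at least 1, an adjusted p under 0.01, the mean of a gene's probe sets, and leaving out each array in turn. Scaling to equal hybridisation controls was added after these controls were seen to differ between the groups.

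The test was tried on simulated data with the real levels and spread, in which 200 of 13680 genes were changed. It recovered 48% of the 100 genes changed by 1 on the log2 scale and 77% of the 100 changed by 2, and called 4 of the unchanged probe sets. In the real data 53.8% of genes were called, so the adjustment there was less strict and these recovery rates do not carry over. A shift of -0.5 put into the 30 mitosis genes was called by camera with both kinds of correlation, with 0 other lists called. As simulated probe sets were drawn independently, this does not test false calls among lists of correlated genes.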

Results

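Kasumi-1 is an acute myeloid leukaemia line that carries the RUNX1-RUNX1T1 fusion, and HHT is a plant alkaloid that blocks translation elongation. Its messenger RNA was profiled after 24 h in 20 nM HHT or vehicle, on 3 arrays per condition. The series title ties HHT to MYC expression and to NF-kB repressing factor, encoded by NKRF. Correlations of log2 signal across probe sets, which are not independent replicates, were 0.917 to 0.935 within a group and 0.901 to 0.910 between groups. The 3 vehicle arrays had medians of 5.96, 5.86 and 5.82 and the 3 HHT arrays of 5.78, 5.62 and 5.53. Taken in the order of the sample titles, the medians fell at every step. A drift along that order cannot be told apart from a small effect of HHT.

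MYC transcript fell by 4.40 on the log2 scale (SE 0.0958, adjusted p = 5.29e-09), a 21.0-fold lower signal. Its mean was 14.15 ± 0.0123 in vehicle (SD, n = 3) and 9.75 ± 0.220 in HHT (SD, n = 3). NKRF differed by -0.22 (SE 0.0885, adjusted p = 0.0689) and was not called, with means of 10.79 ± 0.126 and 10.57 ± 0.108. It was called without vehicle replicate 2 (-0.28, adjusted p = 0.0365), without HHT replicate 1 (-0.28, adjusted p = 0.0363) and after quantile normalization (-0.32, adjusted p = 0.0124). Its sign turned with equal medians (0.02, adjusted p = 0.897) and with equal hybridisation controls (0.07, adjusted p = 0.633), where it was not called. RELA, the p65 subunit of NF-kB, rose by 1.02 (SE 0.0760, adjusted p = 1.81e-06), from 10.09 ± 0.0989 to 11.11 ± 0.0289. KIT, a receptor tyrosine kinase, fell by 0.62 (SE 0.0658, adjusted p = 2.30e-05), from 14.83 ± 0.133 to 14.22 ± 0.0431. Its value was -0.38 with equal medians, -0.33 with equal hybridisation controls and -0.23 after quantile normalization, called under each. In vehicle KIT lay between 14.7 and 15.2, where 34 genes other than ribosomal protein genes had a median change of -0.43. A lower signal at this level was thus not particular to KIT. RUNX1T1 differed by -0.03 (SE 0.0510, adjusted p = 0.679) and was not called, but its value was 0.23 after quantile normalization and 0.26 with equal hybridisation controls, both called. A dimmer RUNX1T1 probe set fell by 1.53 (adjusted p = 0.0232). This is its measured change, with an HHT mean of 4.78, just below the filter level. The gene's other probe sets, at -0.08 (the brightest of these), 0.22, 0.38, -0.01 and -0.70, were not called. The mean of all its probe sets, the dim one included, differed by -0.25 (adjusted p = 0.0284). RUNX1 was not analysed here, as no probe set was annotated to it alone.

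**Figure D1:**
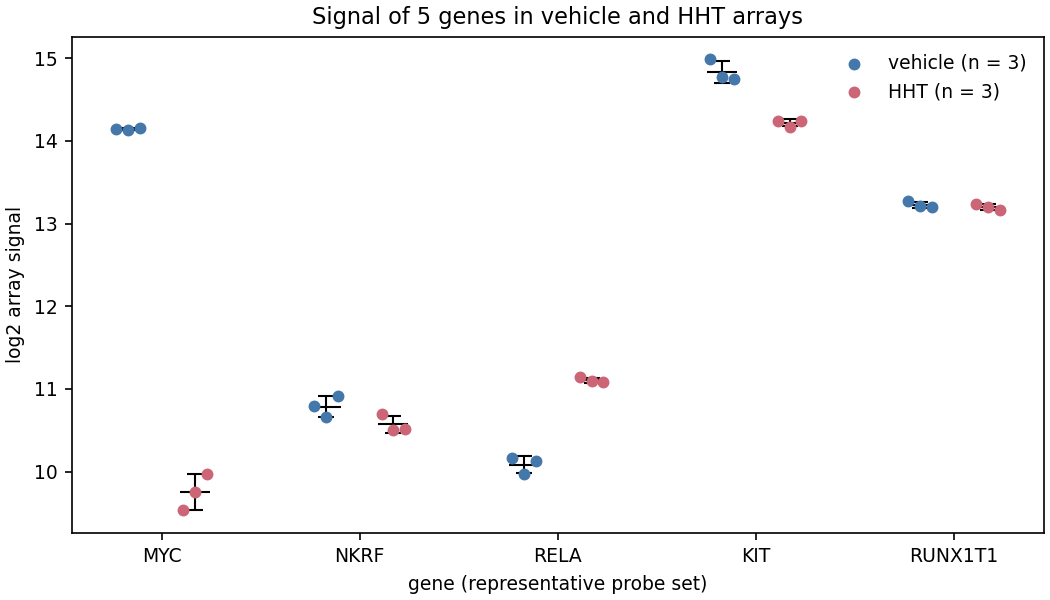
Log2 array signal (vertical axis) of the representative probe sets of 5 genes (horizontal axis) in vehicle and HHT arrays, with 1 point per array and bars for the mean and SD (n = 3 per group). MYC lies at 14.15 in vehicle and 9.75 in HHT, while the NKRF arrays of the groups overlap.

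Across the array, 4017 genes rose and 3280 fell of 13572 tested, and 15184 probe sets changed, 7534 up and 7650 down. The groups did not overlap for 62.2% of genes, where chance gives 10%. With an absolute log2 change of at least 1 also required, 1297 genes rose and 806 fell. The balance depended on the scaling. Genes that rose made up 55.1% of calls as deposited, 74.7% with equal medians (5062 up, 1718 down) and 76.4% with equal hybridisation controls (5640 up, 1741 down). These scalings moved the median of all genes from 0 to 0.24 and 0.28, and each list median by the same amounts. The 18 hybridisation control probe sets, for transcripts added to each sample, averaged 11.98 ± 0.0282 in vehicle and 11.70 ± 0.0598 in HHT, a difference of -0.28 (exact permutation p = 0.1, two-sided, the smallest possible with 3 against 3). All 18 were lower in HHT. The 12 poly-A control probe sets, for added polyadenylated transcripts, were also all lower, with averages of 7.96 ± 0.191 and 7.48 ± 0.122. They differed by -0.48 (exact permutation p = 0.1, two-sided), or by -0.20 relative to the hybridisation controls. The 6 control probe sets for ACTB and GAPDH were all lower too, with averages of 13.89 ± 0.0720 and 13.29 ± 0.0451, a difference of -0.60 (exact permutation p = 0.1, two-sided), or -0.32 relative to the hybridisation controls. The 3' minus 5' signal, a sign of RNA quality, averaged 0.18 ± 0.0365 in vehicle and 0.12 ± 0.0618 in HHT for GAPDH (exact permutation p = 0.3, two-sided). For ACTB it averaged 2.72 ± 0.0468 and 2.79 ± 0.109 (exact permutation p = 0.5, two-sided).

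By fitted log2 change, the rule for named genes took MYC, ADM5, ARHGAP22, PYCR3, CDR2L and DDN among the genes that fell. ADM5, ARHGAP22, PYCR3 and CDR2L ended below the filter level and were at least 5.97-fold, 9.95-fold, 4.29-fold and 8.70-fold lower. Among those that rose, it took PLAT (tissue plasminogen activator), TMEM71, SYNE1 (a nuclear envelope protein), ARID3B, TXLNB and APBA2. All except TXLNB started below that level. TMEM71 was at least 11.8-fold higher, SYNE1 at least 6.38-fold, APBA2 at least 6.28-fold, PLAT at least 5.80-fold and ARID3B at least 4.48-fold. As these are bounds, no order of size follows. PLAT, ARID3B and PYCR3 passed the filter in only 3 of the 6 fits that left out an array, and SYNE1 in 5. Genes with both means above that level, taken the same way after the values were seen, were MYC, DDN, INHBE, the amino acid transporter SLC7A5, the nucleoside transporter SLC29A2 and the long noncoding RNA DANCR among those that fell. SLC7A5 fell by 3.14 (SE 0.0781), from 12.19 ± 0.0783 to 9.05 ± 0.0859. Of those that rose, ZC3H6 changed by 3.76 (SE 0.233), LPAR4 by 3.34 (SE 0.254), MAML2 by 3.31 (SE 0.271) and TTC38 by 3.31 (SE 0.246). With 1 array below the level set to it, TXLNB was at least 12.1-fold and LOC101929174 at least 9.77-fold higher, and DDN at least 12.6-fold and INHBE at least 8.93-fold lower.

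Genes that MYC is known to activate were lower as a group. Of 25 measured, 23 fell and none rose (24 fell adjusted over the list alone), with a median of -0.98. The set test gave an adjusted p of 6.79e-12, and adjusted p = 0.152 with an estimated correlation. HSPE1, a mitochondrial chaperonin, fell by 2.14 (SE 0.0724) and TCOF1, a nucleolar factor, fell by 1.73 (SE 0.165). In the MYC and MAX network, 6 of 11 genes fell and 2 rose, the same adjusted over the list alone, with a median of -0.29 (adjusted p = 0.0835), and the list was called after quantile normalization (-0.34, adjusted p = 0.0403). It was not called with equal medians (-0.05, adjusted p = 0.109) or equal hybridisation controls (-0.0037, adjusted p = 0.102). MYCN fell by 1.53 (SE 0.0666), from 11.74 ± 0.0552 to 10.21 ± 0.0385. Its other probe set, at -0.07, was not called, and the mean of both was -0.80 (adjusted p = 0.00794).

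Members and targets of the NF-kB pathway were higher as a group: 15 of 24 rose and 2 fell (16 and 2 adjusted over the list alone), with a median of 0.58. The adjusted p was 0.00867, and adjusted p = 0.226 with an estimated correlation. CCL4 and CXCL3, both chemokines, were at least 2.35-fold and 2.81-fold higher, from vehicle means of 3.39 ± 1.76 and 4.42 ± 1.78. CCL4 passed the filter in only 2 of the 6 fits that left out an array, and did not after quantile normalization. CXCL3 was 2.43-fold higher without vehicle replicate 3. It was not called without HHT replicate 1, 2 or 3 (adjusted p = 0.0643, 0.0703 and 0.0571) or without a variance trend (adjusted p = 0.0897). Interferon response genes had the highest median, 1.55, with 14 of 18 higher and none lower, also adjusted over the list alone (adjusted p = 4.76e-06, and adjusted p = 0.152 with an estimated correlation). IFIT2 rose by 2.50 (SE 0.0824), from 8.93 ± 0.0728 to 11.43 ± 0.0855, and OAS2, an antiviral enzyme, by 2.36 (SE 0.258). Of its other probe sets, 1 rose by 2.03 and 1, at 0.16, was not called. Of 20 immediate early genes, 11 rose and 3 fell (12 and 3 adjusted over the list alone), with a median of 0.60 (adjusted p = 0.0243, and adjusted p = 0.244 with an estimated correlation). NR4A3 and KLF2, both transcription factors, were at least 4.13-fold and 3.87-fold higher. NR4A3 passed the filter in only 3 of the 6 fits that left out an array. A second NR4A3 probe set, at 0.47, was not called (adjusted p = 0.616). KLF2 was 2.98-fold higher without vehicle replicate 1, and was not called without a variance trend (adjusted p = 0.0782).

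Cholesterol synthesis genes had the lowest median, -1.77. Of 16 measured, 14 fell and 1 rose, also adjusted over the list alone (adjusted p = 6.61e-09, and adjusted p = 0.152 with an estimated correlation). INSIG1, a sterol-regulated membrane protein, fell by 2.93 (SE 0.0742) and TMEM97 fell by 2.92 (SE 0.0666). In glycolysis, 13 of 20 genes fell and 3 rose (14 and 3 adjusted over the list alone), with a median of -0.50 (adjusted p = 0.000832, and adjusted p = 0.141 with an estimated correlation), or -0.26 with equal medians and -0.22 with equal hybridisation controls. The glucose transporter SLC2A1 fell by 1.40 (SE 0.179) and PFKP fell by 1.05 (SE 0.0603). Of 33 oxidative phosphorylation genes, 14 fell and 5 rose (16 and 6 adjusted over the list alone). Their median was -0.16 (adjusted p = 0.0277, and adjusted p = 0.456 with an estimated correlation). The list was not called with equal medians (0.08, adjusted p = 0.576), after quantile normalization (0.09, adjusted p = 0.355) or with equal hybridisation controls (0.13, adjusted p = 0.932). Its call was also lost without HHT replicate 1 (-0.14, adjusted p = 0.0677), without a variance trend (adjusted p = 0.0627) and from the means of probe sets (adjusted p = 0.0664). COX6C fell by 0.57 (SE 0.0606), with called values of -0.33 with equal medians, -0.29 with equal hybridisation controls and -0.20 after quantile normalization. COX7A2 fell by 0.51 (SE 0.0611) and was not called with equal medians (adjusted p = 0.0853) or after quantile normalization (adjusted p = 0.0591).

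Genes of DNA replication fell: 29 of 35 were lower and none higher, also adjusted over the list alone, with a median of -0.71 (adjusted p = 1.62e-11), or -0.47 with equal medians and -0.42 with equal hybridisation controls. This was the only list called with an estimated correlation (adjusted p = 0.0332). FEN1, a flap endonuclease, fell by 1.77 (SE 0.0638) and UHRF1 fell by 1.64 (SE 0.0565). Of 30 mitosis genes, 11 fell and 6 rose (12 and 6 adjusted over the list alone). Their median was -0.09 (adjusted p = 0.334) and was above 0 under the other 3 scalings. It was -0.05 without vehicle replicate 2. HMMR rose by 1.11 (SE 0.0521) and BUB1 by 0.80 (SE 0.0680). Of 11 replication-dependent histone genes, 1 rose and 1 fell (1 and 0 adjusted over the list alone), with a median of 0.51 (adjusted p = 0.519), or 0.07 with the 60% filter. The other 9 were not called. Vehicle means ran from 4.54 (H2AC8) to 9.36 (H2BC12), and the dim members leave the direction of the list open. H2AC6 rose by 1.49 (SE 0.240). H2BC12 fell by 0.32 (SE 0.109), a call lost without vehicle replicate 1 or 2 or HHT replicate 1 or 2 (adjusted p up to 0.118) and with equal medians (-0.08, adjusted p = 0.699), equal hybridisation controls (-0.04, adjusted p = 0.834) or no variance trend (adjusted p = 0.0652).

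Ribosome biogenesis factors fell in 28 of 37 cases and rose in 2, also adjusted over the list alone, with a median of -0.47 (adjusted p = 9.68e-07, and adjusted p = 0.0513 with an estimated correlation), or -0.23 with equal medians and -0.18 with equal hybridisation controls. POLR1A, the large subunit of RNA polymerase I, fell by 2.28 (SE 0.162) and WDR3 fell by 1.52 (SE 0.0728). Of 34 ribosomal protein genes, 33 were called lower, also adjusted over the list alone, with a median of -0.31 and an SD of 0.0459 between genes. The set test gave an adjusted p of 2.00e-07, and adjusted p = 0.425 with an estimated correlation. The list was not called after quantile normalization (0.05, adjusted p = 0.365), and was called at -0.07 with equal medians (adjusted p = 0.00833) and -0.03 with equal hybridisation controls (adjusted p = 0.0203). Camera compares a list with the other genes. The median of all genes was 0.24 with equal medians and 0.28 with equal hybridisation controls. These calls thus place the list below other genes and do not by themselves show a fall. RPL12 differed by -0.43 (SE 0.0605) and RPL7 by -0.38 (SE 0.0667), neither called under the other 3 scalings. Of 34 translation factors, 22 fell and 4 rose (22 and 5 adjusted over the list alone), with a median of -0.25 (adjusted p = 0.000852, and adjusted p = 0.226 with an estimated correlation). The list was not called after quantile normalization (0.02, adjusted p = 0.542) or with equal hybridisation controls (0.03, adjusted p = 0.0819), and was called at -0.01 with equal medians (adjusted p = 0.0430). That call, too, is relative to the other genes. EIF4EBP1, which binds the cap-binding factor, fell by 2.30 (SE 0.0645), and EIF2B2 rose by 1.45 (SE 0.0625). Aminoacyl-tRNA synthetases fell in 12 of 17 cases and rose in none (13 fell adjusted over the list alone), with a median of -0.37 (adjusted p = 0.000258, and adjusted p = 0.226 with an estimated correlation), or -0.13 with equal medians and -0.08 with equal hybridisation controls. VARS1 fell by 1.45 (SE 0.118) and IARS1 fell by 1.32 (SE 0.0525). Of 7 snoRNA host transcripts, 4 fell and 3 rose, also adjusted over the list alone, with a median of -0.49 (adjusted p = 0.460), and the list was called from the means of probe sets (-0.43, adjusted p = 0.0429). The median was -0.10 with the 60% filter (adjusted p = 0.614). DANCR fell by 2.99 (SE 0.0936) and SNHG4 fell by 1.83 (SE 0.405).

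Lists of the integrated stress response, endoplasmic reticulum chaperones and heat shock genes were lower as groups, though not in every member. Of 24 integrated stress response genes, 16 fell and 4 rose (17 and 4 adjusted over the list alone), with a median of -0.65 (adjusted p = 3.50e-05, and adjusted p = 0.226 with an estimated correlation), or -0.41 with equal medians and -0.37 with equal hybridisation controls. SLC7A5 led the list, and STC2 fell by 2.34 (SE 0.157). The 4 that rose were DDIT3 (1.16), SLC3A2 (0.69), PPP1R15A (0.64) and ATF3 (0.51), and ATF4 (-0.15) was not called. Endoplasmic reticulum chaperones and their regulators fell in 13 of 19 cases and rose in 2 (14 and 2 adjusted over the list alone), with a median of -0.56 (adjusted p = 6.76e-05, and adjusted p = 0.0734 with an estimated correlation), or -0.32 with equal medians and -0.28 with equal hybridisation controls. PDIA4, a disulfide isomerase, fell by 1.72 (SE 0.0818). ERN1, a sensor of unfolded proteins, rose by 1.91 (SE 0.124), although its other probe sets, at -0.10 and 0.05, were not called. Of 12 heat shock genes 9 fell and none rose, also adjusted over the list alone, with a median of -0.54 (adjusted p = 5.76e-05, and adjusted p = 0.0734 with an estimated correlation), or -0.30 with equal medians and -0.255 with equal hybridisation controls. HSP90AB1 fell by 1.67 (SE 0.0636) and FKBP4 fell by 1.64 (SE 0.0996). Of 27 proteasome subunits, 12 fell and 6 rose (13 and 6 adjusted over the list alone), with a median of -0.12 (adjusted p = 0.291) that was above 0 under the other 3 scalings. The median was -0.04 without vehicle replicate 1. PSMB5 fell by 0.88 (SE 0.0764) and PSMD1 fell by 0.56 (SE 0.0729), the second called at -0.32 with equal medians and -0.27 with equal hybridisation controls.

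p53 targets went both ways, with 10 of 20 higher and 5 lower (11 and 5 adjusted over the list alone), a median of 0.34 and an adjusted p of 0.319. RRM2B, a ribonucleotide reductase subunit, rose by 1.20 (SE 0.124), and the nuclease AEN fell by 1.17 (SE 0.126). In the BCL2 family and caspases, 9 of 18 rose and 3 fell, also adjusted over the list alone, with a median of 0.27 (adjusted p = 0.431). BCL2, which restrains apoptosis, fell by 1.35 (SE 0.0793), and BID, which promotes it, fell by 1.02 (SE 0.0666).

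Myeloid granule protein genes fell in 4 of 7 cases and rose in none, also adjusted over the list alone, with a median of -1.22 (adjusted p = 0.0156, and adjusted p = 0.244 with an estimated correlation). MPO (myeloperoxidase) fell by 1.76 (SE 0.0891), from 14.39 ± 0.0765 to 12.63 ± 0.198, and ELANE fell by 1.43 (SE 0.338). Of 16 myeloid maturation genes, 2 rose and 1 fell, also adjusted over the list alone. Their median was 0.09 and their mean -0.06, and the set test, in the upward direction, gave an adjusted p of 0.912. The median was -0.05 without HHT replicate 1 and 0.26 without vehicle replicate 3. CEBPA, a myeloid transcription factor, rose by 0.74 (SE 0.141). CSF1R fell by 1.16 (SE 0.350), a call lost without vehicle replicate 1 (adjusted p = 0.0577) or HHT replicate 3 (adjusted p = 0.0599) and with equal hybridisation controls (-0.87, adjusted p = 0.0771). Of 20 stem, progenitor and leukaemia genes, 9 fell and 5 rose, also adjusted over the list alone, with a median of -0.30 (adjusted p = 0.0719). The list was called with equal medians (-0.07, adjusted p = 0.0430) and with equal hybridisation controls (-0.02, adjusted p = 0.0359). These calls place the list below the other genes and do not by themselves show a fall. The list's median was -0.54 without vehicle replicate 2 (adjusted p = 0.0683) and -0.50 without a filter (adjusted p = 0.0512). TAL1 fell by 2.08 (SE 0.0772) and MEIS1 rose by 1.48 (SE 0.280), both of them transcription factors of blood progenitors. MEIS1 was not called from the mean of its probe sets (1.11, adjusted p = 0.0586).

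Camera called none of the 3 marker lists of other cell types that it tested. Fry, which does not compare a list with other genes, called the lymphoid list (adjusted p = 0.00135) and the stromal and epithelial list (adjusted p = 0.00647), both downward. Of 8 lymphoid markers, 2 rose and 2 fell, also adjusted over the list alone, with a median of -0.27 (adjusted p = 0.767), or 0.01 with equal hybridisation controls. The median was -0.17 without HHT replicate 3 and -0.06 from the means of probe sets. CD247 fell by 2.48 (SE 0.128) and NKG7 was at least 3.84-fold higher. Of 7 stromal and epithelial markers 2 fell, also adjusted over the list alone, with a median of -0.50 (adjusted p = 0.263). The median was -0.76 without HHT replicate 1 and -0.33 without HHT replicate 2, and between -0.26 and -0.22 under the other 3 scalings. EPCAM fell by 0.76 (SE 0.0556), or by 0.49 after quantile normalization and 0.48 with equal hybridisation controls, while COL1A1 (-0.86, SE 0.281) was not called without vehicle replicate 2 or 3 or HHT replicate 3 (-0.54 without the last, adjusted p = 0.0813), nor from the mean of its probe sets (-0.30, adjusted p = 0.672). Its call was also lost with equal medians (-0.62, adjusted p = 0.0787), with equal hybridisation controls (-0.58, adjusted p = 0.129) and without a variance trend (adjusted p = 0.0695). Of 5 erythroid markers 1 fell, and 0 adjusted over the list alone, with a median of -0.25 (adjusted p = 0.667), or 0.03 with equal hybridisation controls. It was -0.05 and -0.40 without vehicle replicate 1 and 3, and -0.04, -0.45 and -0.53 without HHT replicate 1, 2 and 3. The gene that fell, KLF1 (-0.82, SE 0.306), was not called when any 1 array was left out (adjusted p = 0.0562 to 0.140) or under any of the other 3 scalings, nor without a filter (adjusted p = 0.111) or with array weights (adjusted p = 0.0533). None of the 3 megakaryocyte markers (median -0.34) or of the 2 markers of mast cells, basophils and eosinophils (median -0.32) was called, over all genes or adjusted over the list alone.

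**Figure D2:**
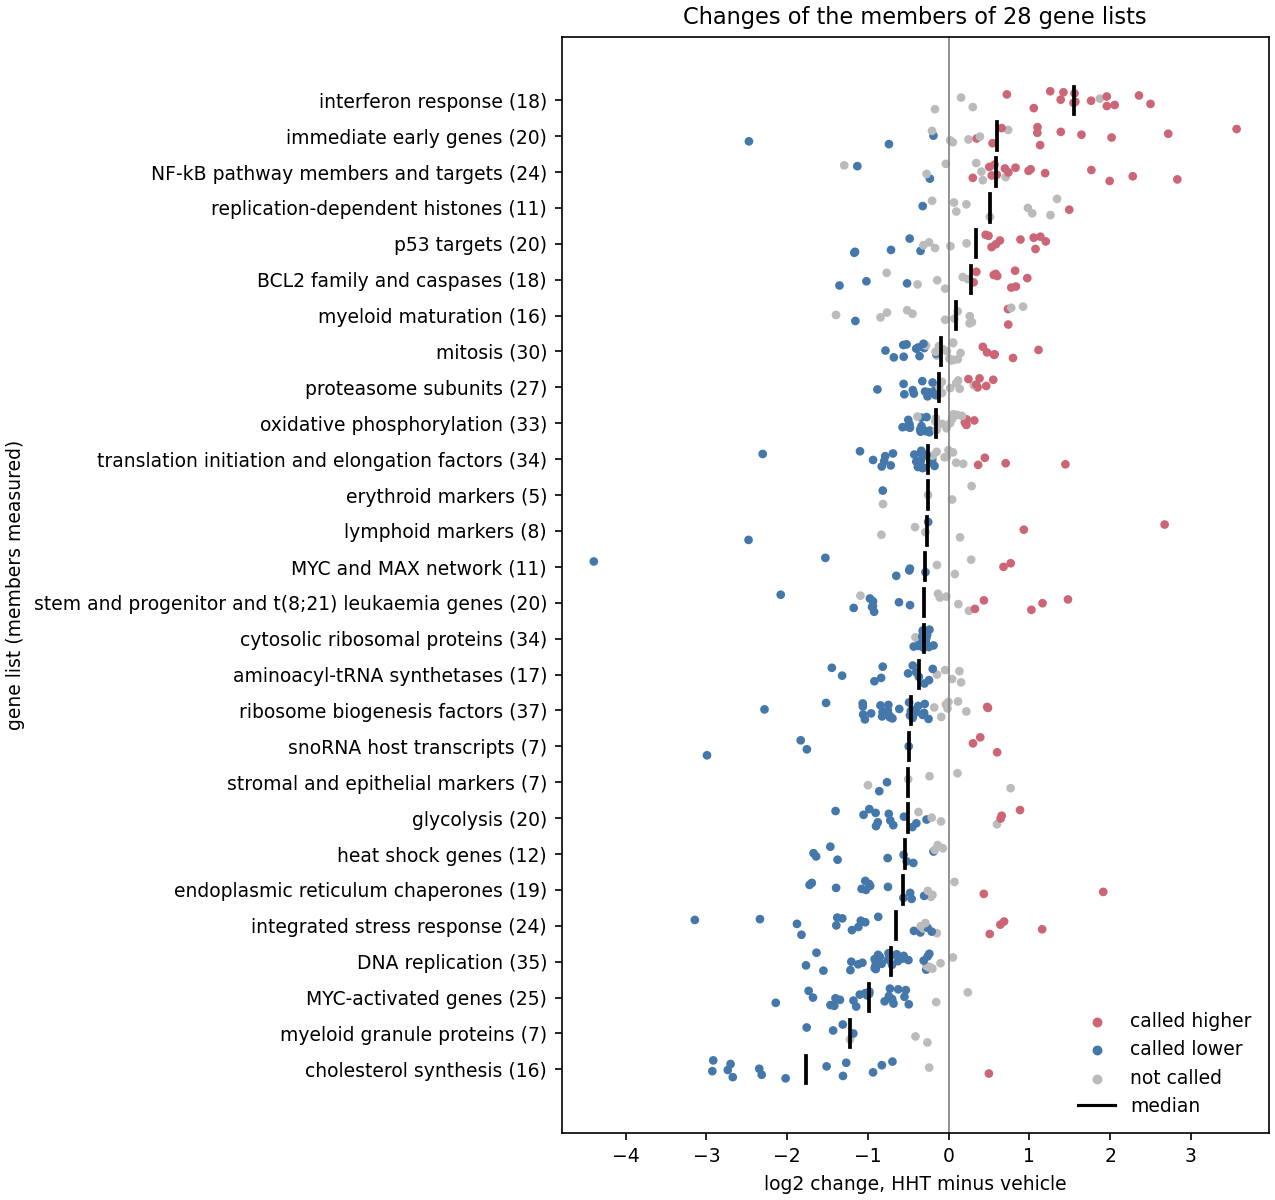
Log2 change from vehicle to HHT (horizontal axis) of the measured members of 28 gene lists (vertical axis), with 1 point per gene coloured by its call and a black line at each median. Medians run from -1.77 for cholesterol synthesis to 1.55 for the interferon response.

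**Figure D3:**
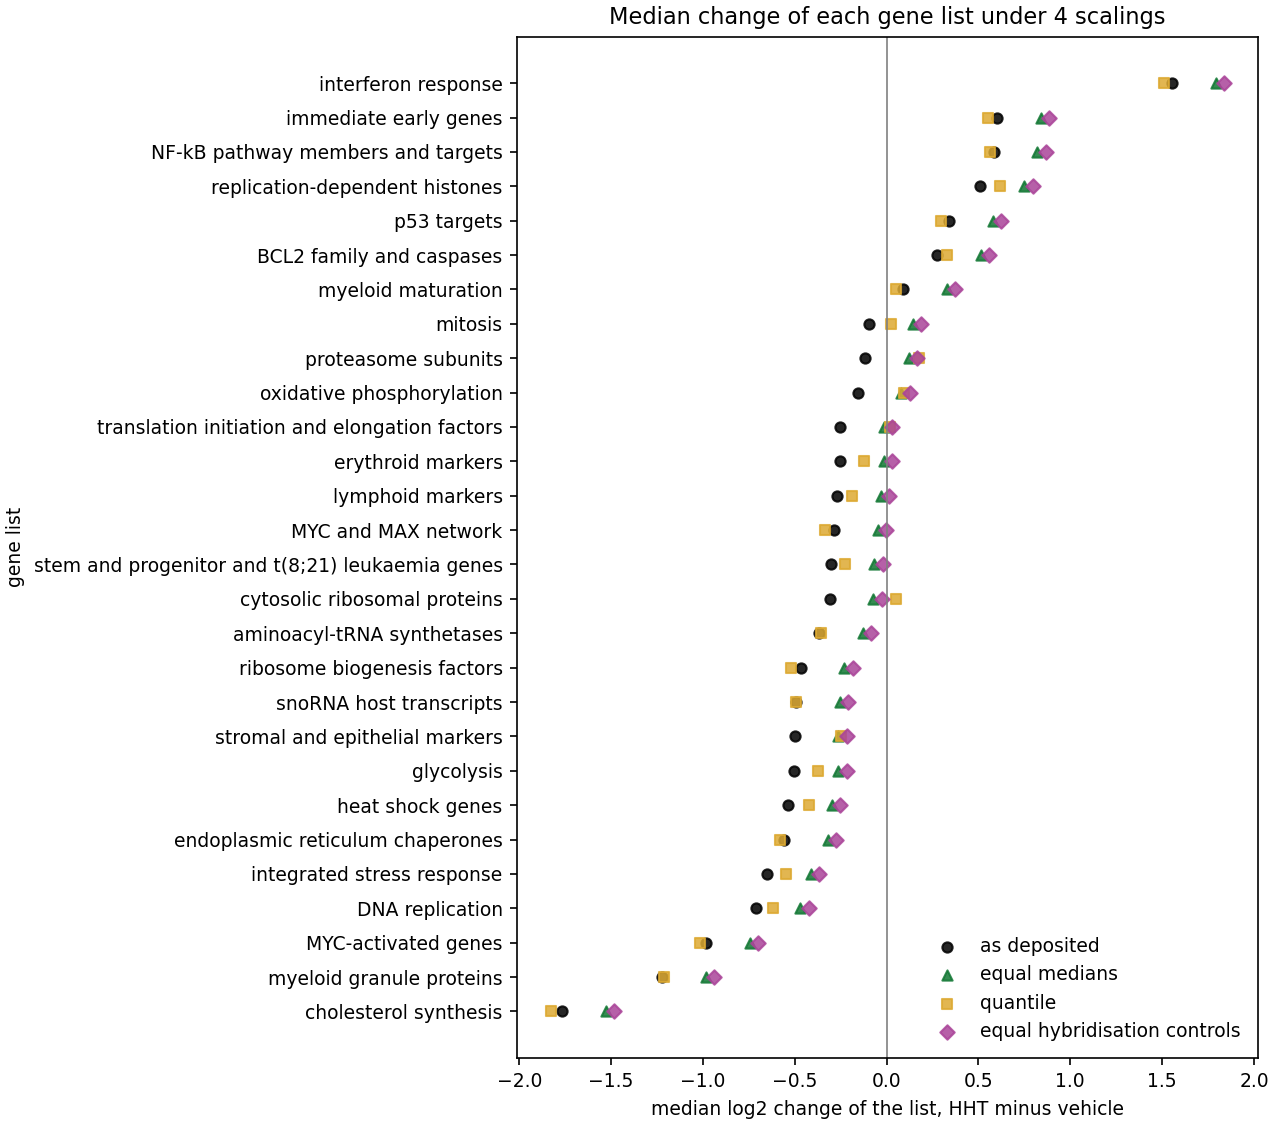
Median log2 change of each of the 28 lists (horizontal axis) with values as deposited, with equal medians, after quantile normalization and with equal hybridisation controls. The interferon median lies between 1.51 and 1.84, and the ribosomal protein median between -0.31 and 0.05.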

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

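The look at the control probe sets was chosen after the values were seen. Of the 6 control probe sets for ribosomal RNA, which entered no comparison, 1 was higher on all HHT arrays than on all vehicle arrays, by 0.30 on the log2 scale, from 13.94 to 14.24. Another 2 were lower on all HHT arrays, with differences of -0.55 and -0.40. Over all 6, the groups differed by -0.08 (exact permutation p = 0.3, two-sided, with 0.1 the smallest possible).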

How the results depend on the processing

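Scaling to equal hybridisation controls was chosen after seeing the data. MYC was lower and called under every alternative run. Genes lower numbered 1718 with equal medians, 1741 with equal hybridisation controls and 806 with an absolute log2 change of at least 1, where 1297 were higher and 5057 probe sets changed. Of genes called in the main setting, 5735 were called in the same direction with equal medians, 5758 with equal hybridisation controls 6575 after quantile normalization, which turned 41, and 6044 from the means of probe sets, which turned 30. Leaving out single arrays kept 6383 to 6714 and turned 3 to 5. Quantile normalization gave NKRF a call (-0.32), and leaving out single arrays moved NKRF between -0.28 and -0.15. Its sign turned, uncalled, with equal medians (0.02) and equal hybridisation controls (0.07). RUNX1T1 turned to 0.23 after quantile normalization and 0.26 with equal hybridisation controls. List medians turned to 0.0522 (ribosomal proteins), 0.02 (translation factors) and 0.0928 (oxidative phosphorylation) after quantile normalization, to 0.081 (oxidative phosphorylation) with equal medians, and to 0.0302 (translation factors) and 0.126 (oxidative phosphorylation) with equal hybridisation controls, and none of these was called. Equal medians and equal controls add 1 constant per array, which shows the cause of these turns; for quantile normalization the cause was not tested. Of 16 lists called by camera, 1 was called with an estimated correlation, and fry called 23. Ribosome biogenesis factors (-0.00765), endoplasmic reticulum chaperones (-0.00311) and heat shock genes (-0.0438) had estimated correlations below the preset 0.01 and also lost their calls. A higher correlation between genes thus does not account for these losses. In the simulated data, probe sets were drawn independently. There camera gave the shifted mitosis list an adjusted p of 9.49e-55 with the preset correlation and 0.00156 with the estimated one. DNA replication, with an estimated correlation of -0.00817, went from an adjusted p of 1.62e-11 to 0.0332. The estimated version was thus stricter even without correlated genes, and a call lost under it does not show correlation. What else caused the differences between the set tests was not tested. Among named genes whose call did not change, a pseudocount of 64 moved 24 by over 1.5 times and the means of probe sets 10. By the same measure, list medians moved for 17 lists with equal medians and for 15 with equal hybridisation controls. They moved for 7 lists with a pseudocount of 64, for 6 from the means of probe sets and for 5 without a filter. From the means of probe sets, COL1A1 (-0.30, adjusted p = 0.672) and MEIS1 (1.11, adjusted p = 0.0586) lost their calls. RUNX1T1 gained one there (-0.25, adjusted p = 0.0284). With the replicate number as a block, 4061 genes rose and 3333 fell, and NKRF stayed uncalled (adjusted p = 0.0596), while KLF1 was no longer called (adjusted p = 0.0781). Correlations of same-numbered arrays' deviations from their group means were weak, at 0.0655, -0.0141 and 0.0491. Vehicle replicates 1 and 3 correlated best with the HHT array of the same number, and vehicle replicate 2 with HHT replicate 1. Pairing by number is thus neither shown nor ruled out. The list tests use no fold threshold, so that alternative gave them no value. Signal over background limits the dim probe sets, whose replicates spread most.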

Other observations

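Gene families in this part, and their tests, were chosen after the table of all genes was seen, as were the tests on ribosomal protein, interferon and ZNF genes, except the count behind the one on saturation. The families' p-values thus come from the values that led to their choice and are descriptive only. Fisher's exact test also treats genes as independent. Genes of fatty acid synthesis were lower after HHT, with a median of -1.33. Of 8 measured, 7 fell, against 24.2% of all genes (Fisher's exact test, p = 0.000302). FASN, the fatty acid synthase, fell by 2.85 (SE 0.130) and the desaturase SCD fell by 2.85 (SE 0.0664), whereas SREBF1, a regulator of these genes, differed by 0.13 (adjusted p = 0.341). Camera over the 6 families gave an adjusted p of 5.20e-05, and adjusted p = 0.0512 with an estimated correlation. Of 8 genes of purine synthesis 6 fell (Fisher's exact test, p = 0.00350), with a median of -0.83 (adjusted p = 0.000200, and adjusted p = 0.0512 with an estimated correlation). PFAS fell by 2.90 (SE 0.0834) and GART fell by 1.87 (SE 0.0712), while ATIC differed by 0.01 (adjusted p = 0.936). Of 13 genes for HLA class I, peptide transport and the immunoproteasome, 7 rose and 3 fell (adjusted p = 0.147), with PSMB9 higher by 1.01 (SE 0.0849) and TAP2 lower by 1.84 (SE 0.0960).

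Genes named CEP, many of them centrosomal, rose in 23 of 35 cases (Fisher's exact test, p = 1.50e-05; camera adjusted p = 0.000906, and adjusted p = 0.107 with an estimated correlation), and VPS genes, of vesicle sorting, in 22 of 35 (p = 5.01e-05; camera adjusted p = 0.000282, and adjusted p = 0.0641 with an estimated correlation). The medians were 0.41 for both, and above 0 under all 4 scalings.

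Of 386 zinc finger genes named ZNF, 169 rose and 40 fell, 43.8% against 29.6% of all genes (Fisher's exact test, p = 2.17e-09), with a median of 0.34 (camera adjusted p = 0.000282, and adjusted p = 0.0512 with an estimated correlation). A change that depends on the signal level would not give this: the median exceeded that of 10000 random sets matched on level by 0.31, and the highest random median was 0.20. Probes shared between related genes were argued against by the 503 ZNF probe sets without a suffix for shared probes, whose median was 0.32, against 0.22 for the 178 with one. A biological response to HHT remains a hypothesis, and its mechanism was not tested.

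The interferon genes could be higher because dim probe sets are noisy, but the 9 members with a vehicle mean of at least 8 had a median of 1.42, and 7 of them were called. Scaling is argued against by the lowest median under the 4 scalings, 1.51. A response of the cells to HHT is a candidate explanation that these arrays cannot trace to its trigger.

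The ribosomal protein genes lay close together, and their median minus the change of the hybridisation controls was -0.0268. Minus that of the poly-A controls it was 0.17, a comparison added after both values were seen. As these controls differ, scaling of each array to one trimmed mean may or may not account for the shift. Saturation of bright probe sets stays open. Of 34 other genes at 14.7 to 15.2 in vehicle, 3 differed from the controls by over 0.5, or 8.82%. The 95% exact binomial interval, 1.86% to 23.7%, was added after the count was seen and is too wide to decide. The median change of these 34 genes was -0.43, against -0.31 for the ribosomal protein genes. A lower signal at this level was thus not limited to ribosomal protein genes. Whether ribosomal protein transcripts fell per cell stays open too, since no measure of RNA per cell was used here and the median with equal controls was -0.0268.

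Of the 10 splits of the 6 arrays into 3 and 3, 1 called as many genes, the real one with 7297, and the highest other called 0. With 10 splits the share cannot fall under 0.05. By limma, 8074 genes had an unadjusted p under 0.05 in the real split and 91 to 228 in the others. Each of the other splits mixed vehicle and HHT arrays in both groups. The difference between vehicle and HHT then added to the spread within groups, so few calls were bound to result. These counts therefore do not show how many genes chance alone would call.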
